A study of Mus musculus with 2 samples.

How the data were processed

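Total RNA from the whole stomach of 2 newborn mouse pups of strain B6NCrl was sequenced, 1 library per pup. Per the labels, the pups were born to the same dam, were taken on the day of birth (postnatal day 0), and their sex was not collected. The labels describe separate stomachs, so the 2 libraries were treated as biological replicates of 1 group, named pup 1 and pup 2 by the replicate numbers in the labels. Per the labels' protocols, RNA was extracted with a mirVana kit, the library was made from 10 ng of RNA above 200 nucleotides, spike-in controls were added, and a manual for the SMARTer Ultra Low kit is among the linked protocols.

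The authors deposited 1 gene table and 1 transcript table per library, on build mm10 with the GENCODE M4 annotation, per the text deposited with each sample. The aligner, the quantification program and their versions are not given in the sources used here; the column names are those that RSEM writes. The expected counts that the authors deposited are estimated reads per feature, not scaled for depth, in which reads shared by several genes are divided among them. The TPM values that the authors deposited are scaled to the same total in each library over all features, spike-ins and tRNA entries included, and each comes with a posterior mean estimate and a credibility interval. The FPKM values that the authors deposited are per kilobase of effective length and per total reads. The isoform share in the deposited transcript tables is the percent of a gene's TPM in each transcript. For long genes the effective length was the length minus 99, as for reads of 100 bases. Strandedness is not given in the sources used here, so overlapping and antisense genes were not told apart.

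Each gene table held 69691 features: 43346 genes with an Ensembl ID, 26248 tRNA entries with a number as ID and 97 spike-ins. Gene symbols, types and positions came from GENCODE M21, a later annotation of the same assembly, matched on IDs without version. This matched 42462 genes and left 884, which held 0.181% and 0.186% of the counts of pups 1 and 2. The expected counts summed to 51524479 in pup 1 and 49983574 in pup 2. A count of 0 allows up to 3 counts, which is a CPM (counts scaled to the library total) of 0.0582 in pup 1 and 0.0600 in pup 2. Such floors, and the exact binomial intervals given for ratios of reads, cover counting error only, since reads amplified by PCR are not independent molecules.

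A gene was called detected at a TPM of at least 1 in both pups. Ratios between pups are log2((TPM of pup 2 + 1)/(TPM of pup 1 + 1)), which understates the difference of genes with low levels. Agreement was measured as Pearson's r of log2(TPM + 1) and Spearman's rho of TPM over protein-coding genes at a TPM of at least 1 in either pup, with no p, since genes are not independent replicates. The spread between pups was estimated with edgeR on expected counts rounded to whole numbers, without spike-ins, after TMM scaling and filterByExpr, as the square root of the common dispersion. A gene differed beyond its quantification error where the deposited 95% intervals of the pups did not overlap, the TPM differed at least 2-fold and the mean expected count was at least 100. This compares 2 libraries and has no replicate check, so no differential test was run and no p was computed.

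Before the data were examined, 34 gene lists were fixed, among them markers of the cell types of the stomach wall and of tissues that can adhere to it. Of the 318 members fixed by symbol, 317 were found. The histone and cytosolic ribosomal protein lists were drawn by symbol pattern. The level of a list is the mean over pups of its median TPM, given with its percentile among the medians of 10000 random lists of the same size from detected protein-coding genes. The fixed lists keep undetected members, so a list with several of them can rank low by its make-up. The difference of a list is the median log2 ratio of its members with a mean TPM of at least 1, given with its percentile among 10000 random lists of the same size. Each random list took its genes from the 200 nearest in mean level. Lists with fewer than 3 such members got no percentile. Percentiles describe these libraries. Genes of a list often vary together, so more lists than 1 in 20 can lie outside the middle 95% of random lists with no difference in cell make-up.

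The genes named were set by a rule fixed at the same time. It took the 3 members of each list with the highest mean TPM and any member that differed at least 2-fold with a mean count of at least 100. It also took the 10 nuclear protein-coding genes with the highest mean TPM, and the 8 largest and 8 smallest log2 ratios among protein-coding and long noncoding genes that differed beyond quantification error. Atp4a, Muc5ac, Gif, Pgc, Gast, Ghrl, Sox2, Barx1, Krt5, Myh11, Xist and Ddx3y were named whatever their level. Other genes named were chosen after their values were seen. A gene that the rule named is not reported here.

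Alternatives changed 1 choice at a time, with 2 exceptions. Poisson intervals came with counts and TMM scaling in place of TPM. For the ratios of genes and lists, TMM scaling came with CPM and DESeq2 scaling with counts in place of TPM, so the 1 was added in another unit. The choices were the thresholds, pseudocounts, filters, fold and count minimum, and FPKM or posterior means in place of TPM. Others were TMM and DESeq2 scaling, DESeq2 dispersion, exact Poisson intervals in place of the deposited ones, and each pup alone. The scripts were tested on counts simulated from the real means and library sizes. A coefficient of variation of 0.1 put into unchanged libraries came back as 0.0999 over 18039 genes. With Poisson intervals and the 2-fold limit, 54.2% of 96 genes changed exactly 2-fold and all of 97 genes changed 4-fold were called, with 1 call among 13730 unchanged genes. The deposited credibility intervals were not simulated. The list rule was tried on the real ratios instead. Of 100 random lists of 12 genes, 5% lay outside the middle 95%, and all of 100 lists shifted by 0.3 lay above it. Genes drawn independently do not test the rule for lists whose genes vary together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.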

Results

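Total RNA of the stomach was profiled in 2 littermate pups on the day of birth. The libraries held 51524479 expected counts in pup 1 and 49983574 in pup 2. The labels name 1 group and no treatment, so the data describe the RNA of the newborn stomach and how far the 2 pups differ. Values are the mean ± SD of the 2 pups (n = 2) unless a pup is named, and positions are on mm10.

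The most abundant nuclear protein-coding gene was Cym, which encodes the milk-clotting protease chymosin, at a TPM of 62296 ± 3554. Pga5, a pepsinogen gene of chief cells, followed at 19594 ± 603. Tff1, a trefoil peptide secreted by surface mucous cells, stood at 12948 ± 104, and Gkn2, a gastrokine of the same cells, at 5400 ± 84.3. The squamous lining of the forestomach was represented by Sprr2a2 at 12069 ± 548, a cornified envelope gene whose reads can be shared with near-identical family members, by Krtdap at 11034 ± 183 and by Cnfn at 4046 ± 156. The others of the 10 highest genes were Bpifb1, a secreted mucosal protein (9581 ± 325), the actin gene Actb (6233 ± 290) and the actin-binding Tmsb4x (5785 ± 343). In all, 13138 of 21474 protein-coding genes (61.2%) and 578 long noncoding RNA genes were detected in both pups.

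Among the epithelial lists, surface mucous genes had a median TPM of 964 ± 160, above 100% of random lists. Muc5ac, the main mucin of adult surface cells, stood at only 2.70 ± 0.269, while Gkn1 stood at 2846 ± 53.2. Chief cell genes had a median of 113 ± 4.91 (percentile 99.9), with the pepsinogen Pgc at 1474 ± 83.0 and Gif, which encodes intrinsic factor, at 143 ± 6.60; 6 of the 7 members were detected. Lipf, the gastric lipase gene, had 0 counts in both pups. The acid-secreting parietal cell was represented by the proton pump subunits Atp4a at 559 ± 55.5 and Atp4b at 768 ± 109 and by the chloride channel family gene Clic6 at 37.3 ± 6.02, with all 12 members detected and a list median of 15.2 ± 1.66 (percentile 61.3). Mucous neck cell genes had a median of 44.3 ± 11.2 (percentile 89.2), with the trefoil gene Tff2 at 779 ± 50.6, Gkn3 at 78.0 ± 20.9 and the mucin Muc6 at 10.7 ± 1.44.

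The endocrine list had a median of 5.38 ± 0.184 (percentile 3.66), and 7 of its 12 members were detected. Ghrl, the precursor of the hunger hormone ghrelin, led it at 406 ± 24.4, above the somatostatin gene Sst at 67.3 ± 0.332 and the gastrin gene Gast at 58.7 ± 19.9. Gastric progenitor genes had a median of 9.77 ± 1.12 (percentile 29.4), led by Cd44 (23.7 ± 0.156), Sox9 (23.0 ± 0.191) and Tnfrsf19 (17.3 ± 0.134). Stomach patterning factors had a median of 12.6 ± 0.0495 (percentile 44.9). Barx1, a transcription factor of the stomach mesenchyme, stood at 156 ± 22.2, Pitx1 at 174 ± 12.8, Klf5 at 107 ± 16 and Sox2, a factor of foregut epithelium, at 10.2 ± 1.68. Stratified squamous genes had a median of 504 ± 50.1, with the keratins Krt4 at 3988 ± 207, Krt13 at 2575 ± 237 and the basal cell keratin Krt5 at 456 ± 32.5, and all 18 members were detected.

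**Figure D1:**
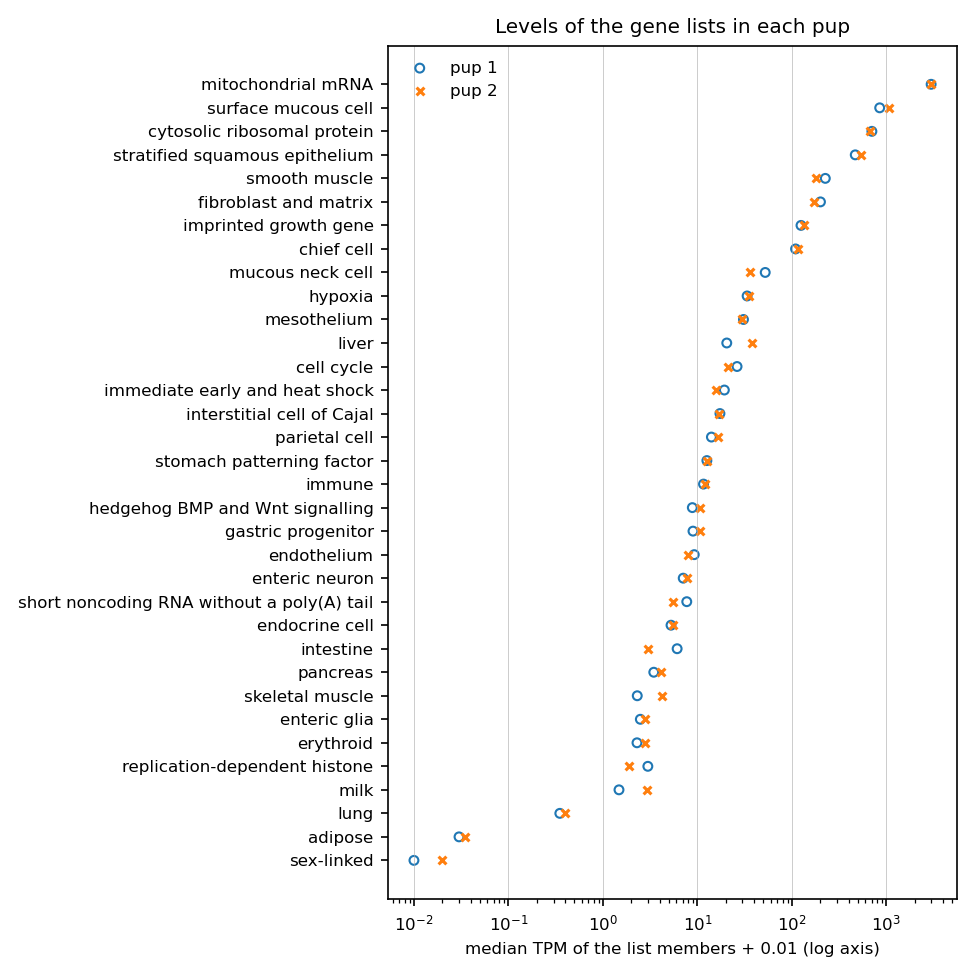
Median TPM of each of the 34 gene lists in pup 1 (circles) and pup 2 (crosses), on a log axis after adding 0.01. Mitochondrial mRNA, surface mucous, ribosomal protein and squamous genes lie highest, and the lung, adipose and sex-linked lists have medians under 1 TPM in both pups.

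In the wall of the stomach, smooth muscle genes had a median of 202 ± 33.5. The smooth muscle actins Acta2 (3139 ± 309) and Actg2 (2872 ± 568) and the tropomyosin Tpm2 (1825 ± 133) led, and the smooth muscle myosin Myh11 stood at 184 ± 25.5. Fibroblast and matrix genes had a median of 187 ± 19.6, with Sparc at 1576 ± 179 and the collagens Col3a1 at 1086 ± 25.7 and Col1a1 at 723 ± 32.8. Enteric neuron genes had a median of 7.39 ± 0.445 (percentile 12.7), with 11 of 12 detected and led by Uchl1 (50.7 ± 1.08), the neuropeptide gene Vip (40.2 ± 7.17) and Tubb3 (21.1 ± 0.191). Enteric glia genes lay at 2.63 ± 0.205 (percentile 0.430), with Erbb3 at 16.1 ± 0.177 and Sox10 at 3.22 ± 0.127. The interstitial cell of Cajal list, the pacemaker cells of gut muscle, had a median of 17.2 ± 0.226 (percentile 60.4), with the channel gene Ano1 at 31.3 ± 5.42, Etv1 at 17.2 ± 0.226 and the receptor Kit at 13.0 ± 1.05.

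Mesothelium genes had a median of 30.2 ± 0.735 (percentile 87.6) and were led by Msln (46.2 ± 8.33), Upk1b (33.6 ± 4.06) and Upk3b (32.8 ± 4.41). Endothelial genes lay at 8.62 ± 0.898 (percentile 21.5), with Plvap at 49.6 ± 2.77, Egfl7 at 45.0 ± 2.81 and Pecam1 at 17.5 ± 0.141. Immune genes lay at 11.8 ± 0.283 (percentile 40.7), with the complement gene C1qb at 68.8 ± 0.636, the neutrophil gene S100a9 at 52.4 ± 5.35 and the lysozyme Lyz2 at 46.0 ± 3.27. Imprinted growth genes had a median of 130 ± 7.57, with Gnas at 773 ± 18.6, the growth factor Igf2 at 287 ± 61.4 and the long noncoding H19 at 285 ± 18.3. Hedgehog, BMP and Wnt signalling genes lay at 9.79 ± 1.36 (percentile 27.7), all 15 detected, led by Sfrp2 (103 ± 2.59), Wnt4 (45.1 ± 8.73) and Sfrp1 (44.7 ± 3.54). Cell cycle genes had a median of 23.8 ± 3.59 (percentile 86.1), with the mitotic kinase Cdk1 at 107 ± 26.1, the replication clamp Pcna at 93.2 ± 1.5 and the cyclin Ccnb1 at 35.0 ± 7.67.

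Lists of neighbouring or contained tissues lay low among random lists except the liver list, and single genes stood above their list. These percentiles partly follow list make-up, since random lists hold detected genes alone. Of the 10 erythroid members found, for example, 5 were detected in both pups. The intestine list had a median of 4.55 ± 2.19 (percentile 1.72), although the apolipoprotein Apoa1 stood at 280 ± 10.2, the fatty acid binding Fabp1 at 180 ± 1.03 and Fabp2 at 17.03 ± 2.05. The pancreas list lay at 3.77 ± 0.453 (percentile 0.530), led by the digestive enzyme genes Ctrb1 (18.9 ± 2.41), Cela2a (17.4 ± 2.62) and Amy2a5 (13.7 ± 10.1). The liver list lay at 29.3 ± 12.5 (percentile 90.0), with the carrier Ttr at 58.8 ± 2.29, the plasma protein gene Ahsg at 34.1 ± 13.4 and the alpha-fetoprotein gene Afp at 34.0 ± 18.7. Skeletal muscle genes lay at 3.28 ± 1.38 (percentile 0.680), with Ckm at 30.1 ± 1.12, Acta1 at 21.5 ± 2.58 and Tnni2 at 15.4 ± 0.0778. Milk genes lay at 2.19 ± 1.03 (percentile 0.3), led by the caseins Csn2 (5.16 ± 3.34) and Csn1s2a (2.62 ± 1.07) and by Wap (3.38 ± 1.60). The lung list lay at 0.365 ± 0.0354, with Scgb1a1 at 10.0 ± 1.06, Ager at 1.44 ± 0.184 and the surfactant gene Sftpc at 0.365 ± 0.0354. The adipose list lay at 0.0225 ± 0.00354, with Fabp4, which endothelium also expresses, at 181 ± 23.4, Cidea at 6.65 ± 0.0424 and the brown fat gene Ucp1 at 2 counts in each pup. The erythroid list lay at 2.53 ± 0.350 (percentile 0.0700), with the globins Hba-a2 at 730 ± 119, Hbb-bs at 479 ± 71.2 and Hba-a1 at 308 ± 56.5; reads of the near-identical globin copies can be divided among them in more than one way.

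Xist, the noncoding RNA of the inactive X chromosome, had a TPM of 17.1 in pup 1 and 16.9 in pup 2, from 12408 and 11801 counts. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 1 count in pup 1 and 3 counts in pup 2, which is at or under the floor.

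Nuclear protein-coding genes held 84.4 ± 0.0583% of TPM, pseudogenes 5.47 ± 0.0270%, mitochondrial protein-coding genes 4.29 ± 0.124%, small noncoding RNA 3.14 ± 0.236%, long noncoding RNA 1.59 ± 0.0450% and mitochondrial rRNA 0.864 ± 0.157%. Of the expected counts, protein-coding nuclear genes held 92.7 ± 0.217%. The mitochondrial mRNA list had a median TPM of 2959 ± 28.4, led by the ATP synthase genes mt-Atp6 (11721 ± 37.3) and mt-Atp8 (9960 ± 300) and by mt-Co1 (3930 ± 126). RNA without a poly(A) tail was present. Rn7s1, the RNA of the signal recognition particle, stood at 13335 ± 1236, Rn7sk, which restrains transcription elongation, at 315 ± 11.5 and Rpph1, the RNA of ribonuclease P, at 121 ± 6.99, while the median of that list was 6.59 ± 1.59 (percentile 16.04). Replication-dependent histone genes had a median of 2.44 ± 0.767 over 64 members, with Hist1h2ap at 1367 ± 389, Hist2h2aa2 at 206 ± 19.5 and Hist1h2bc at 164 ± 11.4; reads of histone copies can be divided in more than one way. Cytosolic ribosomal protein genes had a median of 685 ± 25.9, led by Rpl41 (3117 ± 90.1), Rpl32 (2065 ± 31.3) and Rps19 (1845 ± 4.72). Hypoxia genes had a median of 34.6 ± 1.37 (percentile 95.2), with the glycolytic Ldha at 657 ± 60.3, Pgk1 at 122 ± 13.7 and Bnip3 at 97.2 ± 0.445. Immediate early and heat shock genes had a median of 17.4 ± 2.62 (percentile 71.2), led by Ier2 (72.7 ± 2.25), Jun (72.6 ± 5.25) and Zfp36 (36.0 ± 0.566). The 97 spike-in entries had 249 counts in pup 1 and 337 in pup 2, with 16 seen in both, and their share of the counts was 1.40 times higher in pup 2 (95% exact interval 1.18 to 1.65).

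Most genes stood at close levels in the 2 pups. Over 13506 protein-coding genes, Pearson's r was 0.994 and Spearman's rho 0.993, which are values across genes and not across samples. Of the 13138 detected genes, 97.9% lay within 1.5-fold and 99.5% within 2-fold, and 61 lay beyond. The biological coefficient of variation between the pups was 0.0941 over 17905 genes. The pups still differed by more than sampling: 41.7% of the detected genes exceeded the 95% point of a chi-square test of their counts, against 5% by sampling. This sets the libraries against counting noise alone, without the noise of preparation, and decides nothing on its source. The labels name separate stomachs, and the libraries were counted as 2 samples on that ground. Main transcripts were compared in 7078 protein-coding genes with a TPM of at least 5 in both pups and at least 2 transcripts. Of these, 6634 (93.7%) had the same main transcript in both pups. The median share of the main transcript over the 7078 genes was 73.0% of the gene's TPM. The main transcript of the proton pump gene Atp4a held 90.6 ± 0.0636%, that of Actg2 62.3 ± 6.98%, and that of Kit 63.8 ± 22.7%.

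**Figure D2:**
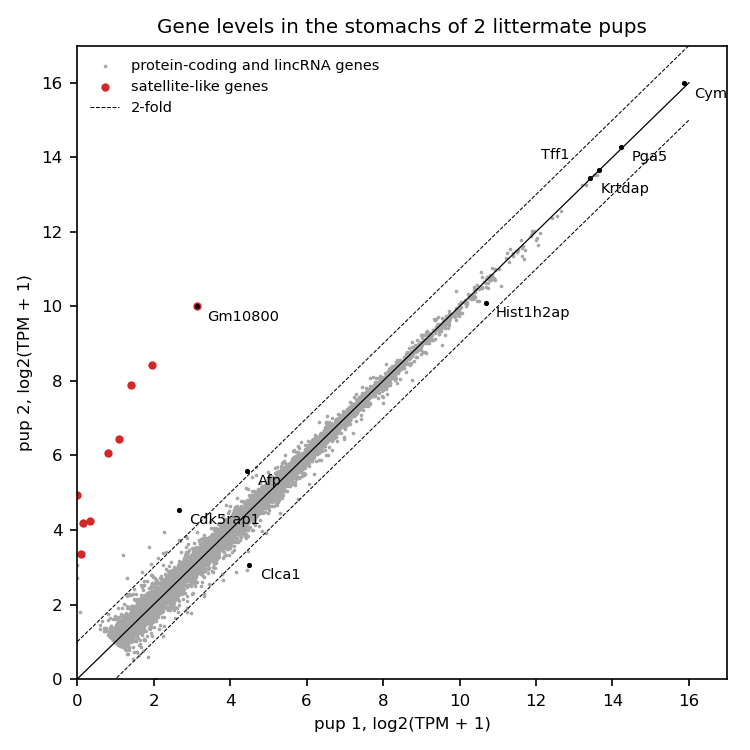
Level of each protein-coding and lincRNA gene with a mean TPM of at least 1 in pup 1 (x) and pup 2 (y), as log2(TPM + 1), with lines at equality and 2-fold. Most genes lie near the line of equality from the lowest levels to Cym, and the 9 satellite-like genes in red, such as Gm10800 at 7.72 TPM in pup 1 and 1027 in pup 2, lie far above it.

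Of 13951 genes with enough counts, 42 were at least 2-fold higher and 17 at least 2-fold lower in pup 2 beyond their quantification error. The largest ratios belonged to a set of predicted genes in satellite repeat regions. Gm10800 (ENSMUSG00000075014.1, chromosome 2, 98666547 to 98667301) had a TPM of 7.72 in pup 1 and 1027 in pup 2, a log2 ratio of 6.88. Gm10801, beside it on chromosome 2, had a log2 ratio of 6.497 and the lincRNA Gm26870 (chromosome 9, 3000282 to 3038313), whose span holds further genes of the set, 6.47. Gm21738 on chromosome 14 had 5.33, and Gm10718 (5.27), Gm10721 (4.95), Gm10719 (4.02) and Gm10717 (3.91) lie on chromosome 9. Low counts in pup 1 make these ratios depend on the processing. With a pseudocount of 0.1, TMM-scaled CPM and DESeq2-scaled counts, Gm10717 had 5.62, 3.05 and 5.84 and Gm10721 8.23, 3.85 and 9.42. The CPM and count settings changed the unit to which 1 is added as well as the scaling. The scaling factors were close to 1, at 0.992 and 1.01 (TMM) and 1.01 and 0.994 (DESeq2) for pups 1 and 2. Gm10721 had 0 counts in pup 1, so that it was at least 233-fold higher in pup 2 against the floor of 3 counts, and Gm10719, with 2.92 counts in pup 1, was 140-fold higher with a counting interval of 46.1 to 661. With Gm11168, chosen after its values were seen, these 9 genes held 390 counts in pup 1 and 46440 in pup 2. Genes of the chemosensory receptor families, which are largely silent outside sensory tissue, had 205 counts in pup 1 and 524 in pup 2, and 53 and 294 of the 1477 such genes had a count.

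Outside that set, the genes next in ratio were chosen after their values were seen. Cdk5rap1 (chromosome 2, 154335380 to 154373010), which encodes an enzyme that modifies mitochondrial tRNA, had a TPM of 5.35 in pup 1 and 22.3 in pup 2. The platelet chemokine gene Ppbp stood at 3.82 and 14.5 and the lipoxygenase Alox15 at 2.71 and 10.6. At the other end, Clca1, a secreted protein of goblet cells, had a TPM of 21.7 in pup 1 and 7.36 in pup 2, a log2 ratio of -1.44. Next came Hist1h2ak (-1.28), the trypsin-like Gm5771 (-1.23), the chemokine Ccl20 (-1.15), Hist1h1b (-1.09), the trypsin gene Try4 (-1.07), Hist1h3d (-1.03) and the kallikrein-related peptidase Klk6 (-1.03).

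Of the 31 gene lists with enough members, 8 lay above and 10 below the middle 95% of matched random lists, against 1.55 by chance if genes varied independently. The liver list had the largest median log2 ratio at 0.80, with 7 of 7 members higher in pup 2: Afp stood at 20.8 in pup 1 and 47.2 in pup 2, the fibrinogen gene Fgb at 2.38 and 5.21, and Ahsg at 24.7 and 43.6. Milk genes had 0.67, with 5 of 5 members higher and Csn2 at 2.79 and 7.52. Skeletal muscle had 0.34 (7 of 7 higher), but 0.15 and inside the range at a mean TPM of at least 5. Erythroid genes had 0.33 (5 of 5), parietal cell genes 0.22 (10 of 12), surface mucous genes 0.20 (6 of 8), patterning factors 0.13 (13 of 18) and squamous genes 0.08 (14 of 18).

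The histone list had the lowest ratio at -0.59, with 41 of 45 members lower in pup 2, among them Hist1h2ap at 1642 and 1093, Hist2h3b at 29.4 and 14.03 and Hist1h2ab at 12.8 and 6.03. Cell cycle genes had -0.37 (9 of 12 lower), with Cdk1 at 126 in pup 1 and 88.8 in pup 2. Mesothelium had -0.27 (3 of 5 lower), pancreas -0.25 (7 of 9), intestine -0.23 (5 of 7), smooth muscle -0.20 (10 of 12), mucous neck cells -0.19 (4 of 4) and ribosomal protein genes -0.06 (59 of 76). Hypoxia genes had -0.12 (7 of 9), but lay inside the range with TMM-scaled CPM (-0.11) and at a mean TPM of at least 5 (-0.08). Immune genes had -0.08 (8 of 13), but lay inside it with TMM-scaled CPM and with DESeq2-scaled counts (-0.06 each). In these lists the brush border phosphatase Alpi stood at 9.83 and 4.89, the lactase Lct at 2.36 and 1.11, and the amylase Amy2a5, whose interval overlapped between pups and whose reads can be shared with its copies, at 20.8 and 6.60. The 13 lists inside the range were interstitial cell of Cajal (0.15), chief cell (0.10), immediate early and heat shock (0.08), enteric glia (0.04), signalling (0.04), endocrine (0.02), enteric neuron (0.02), endothelium (0.02), gastric progenitor (0.01), imprinted (0.00), fibroblast and matrix (-0.02), mitochondrial mRNA (-0.10) and short noncoding RNA (-0.12). The lung (-0.18), adipose (-0.14) and sex-linked (-0.02) lists had too few members for a percentile. With 1 library per pup, none of these differences has a replicate check.

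**Figure D3:**
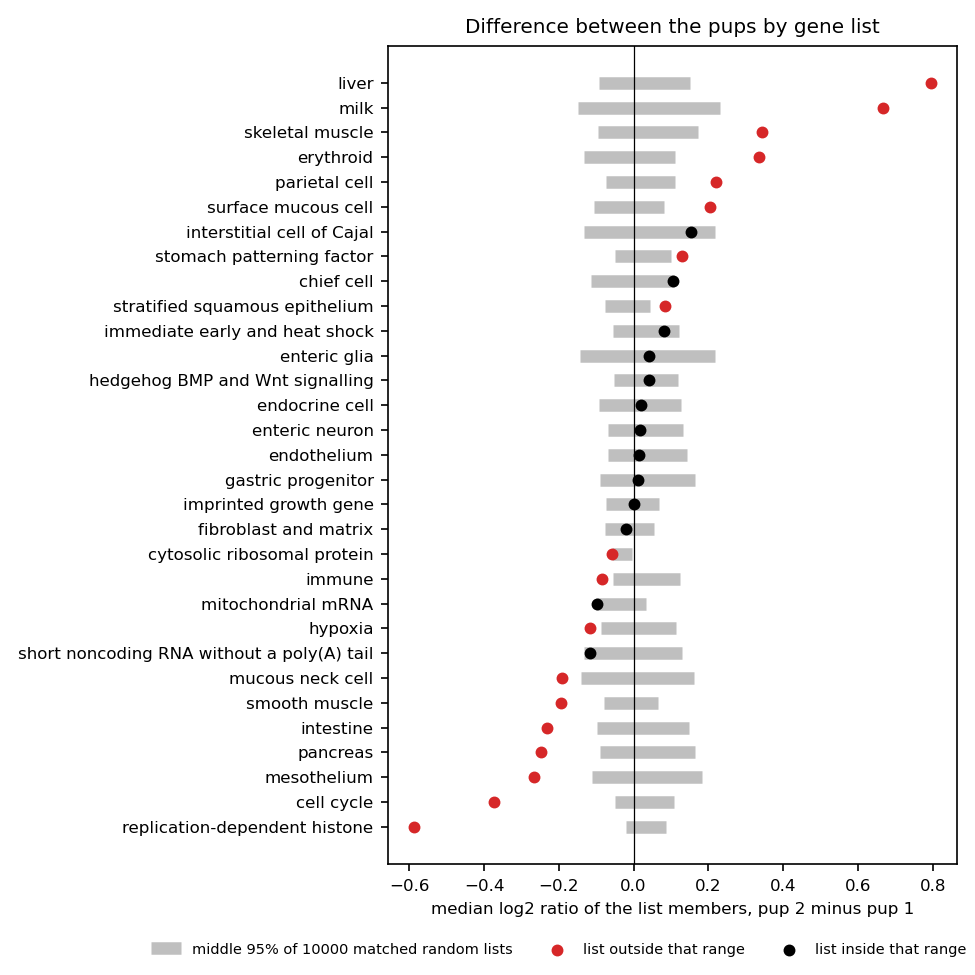
Median log2 ratio of the members of each list, pup 2 minus pup 1 (points), with the middle 95% of 10000 random lists matched on level (grey bars). Liver (0.80) and milk (0.67) genes lie farthest to the right and histone (-0.59) and cell cycle (-0.37) genes farthest to the left.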

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

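Removing the 9 satellite-like genes was chosen after the data were seen; it left 33 genes higher in pup 2. The number of genes that differed beyond quantification error followed its limits, by construction. It was 151 higher and 77 lower in pup 2 at 1.5-fold, 13 and 0 at 3-fold, 112 and 46 at a mean count of at least 10, and 9 and 1 at a mean count of at least 1000. It was 36 and 18 with the median ratio set to 0, and 39 and 24 with Poisson intervals on TMM-scaled counts, which changes the intervals, the unit and the scaling together. The number of protein-coding genes detected ranged from 9569 at a TPM of at least 5 to 15761 at 0.1, and was 13281 and 13363 in each pup alone. Pearson's r ranged from 0.990 to 0.997. The edgeR coefficient of variation ranged from 0.0936 to 0.0994, while the median gene-wise DESeq2 value was 0.0001, its lower limit; the cause was not tested. Protein-coding genes held 92.7% of counts in place of 84.4% of TPM, which divides by length. The same main transcript was found in 91.7% of genes at a gene TPM of at least 1 and in 95.04% at 20, and the median share was 73.27 to 73.36% in each pup alone; the cause was not tested. Of 16 log2 ratios of single genes, 6, all of satellite-like genes, moved by more than 0.5 in 3 settings, and none changed sign. They were higher at a pseudocount of 0.1 and with DESeq2-scaled counts, and lower with TMM-scaled CPM. The DESeq2 and TMM settings changed the unit as well as the scaling, here and for the lists. Of the spike-ins, 6 in place of 16 were seen in both pups at 10 or more counts. No list difference changed sign among those outside the random range. Chief cell genes passed it with TMM-scaled CPM (0.07) and with DESeq2-scaled counts (0.07). Immune genes lost it under both (-0.06 and -0.06), hypoxia genes with TMM-scaled CPM (-0.11) and at a mean TPM of at least 5 (-0.08), and skeletal muscle genes at 5 (0.15). Milk and enteric glia had too few members for that setting. Alternatives for the agreement over transcripts without each pup were not run, since agreement needs both. The SD of log2 ratios was 0.46 at mean counts of 30 to 100 against 0.20 at 1000 to 3000, so low counts limit which differences stand out. No paired analysis was possible because the series has 1 group.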

Other observations

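The test of the fat cell genes, and the limits by spread, by 2-fold members and by genes left out of a list, were chosen only after results were seen. The other bounds were written before, but the satellite-like set and Cdk5rap1 were chosen after their values were seen. The Cdk5rap1 start and the Y-linked tests were first run by other rules than those written. The return to the written rule, after the result was seen, turned the verdict on the Cdk5rap1 start from against to open. The design names no groups to compare, and apart from the sex of the pups and the start of the Cdk5rap1 transcripts no biological explanation was tested.

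Beyond the lists, genes higher in pup 2 included the fibrinogen chains Fga (3.32 TPM in pup 1, 8.59 in pup 2) and Fgg (3.97 and 9.62), kininogen Kng1 (3.75 and 9.45), plasminogen Plg (0.820 and 2.11), vitamin D binding protein Gc (2.20 and 4.79) and Apoh (2.86 and 5.97). The drug-metabolising genes Cyp3a11 (0.560 and 1.92) and Cyp2a5 (6.34 and 12.9) went the same way. Genes lower in pup 2 included the renin gene Ren1 (5.25 and 2.49). Within the lists, Nkx2-5, a transcription factor of the pyloric sphincter, had 46 counts in pup 1 and 8 in pup 2, and the insulin gene Ins2 had 22 and 82. These genes were chosen after their values were seen.

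The satellite-like genes high in pup 2 share sequence: a median of 72.1% of their 24-mers occurred in another gene of the set, against 0% in the highest of 100 random sets matched on length, so they may be 1 repeat counted several times rather than 9 separate changes. Genomic DNA in the pup 2 library is a candidate source of those reads. Chemosensory receptor genes had a share of the counts 2.63 times higher in pup 2 (95% exact interval 2.24 to 3.11), above the bound of 2 set for this explanation. Of these 1477 genes, 53 had a count in pup 1 and 294 in pup 2. The satellite-like set was 123 times higher, but the folds start from unlike pup 1 counts, so the gap between them decides nothing. In all, 3251 features had counts in pup 2 alone against 1130 in pup 1 alone. The test shows more reads from silent genes in pup 2, not that DNA supplied the satellite reads; whether it could give a rise of that size was not tested, and transcription of the repeat stays open.

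For the genes that differ between the 2 pups, a different share of 1 adhering or contained tissue was weighed by the median log2 ratio of each list, with a bound of 1 for and 0.5 against. Erythroid genes had 0.33 (5 of 5 members higher in pup 2, SD of members 0.0757) and skeletal muscle genes 0.34 (7 of 7, SD 0.243). Squamous epithelium genes had 0.0837 (14 of 18, SD 0.192). These lists lay above the random range, but no member was 2-fold apart. Their medians fell short of the 2-fold of the differing genes by more than the spread of their members. A different share moves its genes alike, so this argues against such a share as the source of the 2-fold differences. It does not argue against a smaller difference in share. The squamous list left out 1 differing gene, so there the values cover the listed genes alone. The medians of pancreas (-0.25) and intestine genes (-0.23), both below the random range, and of immediate early and heat shock genes as a sign of RNA handling (0.0799) met the bound against too, but it was wrong to rest on a median. Members were 2-fold apart (Ins2 and Amy2a5 in opposite directions, Alpi and Lct) or went both ways: Nr4a1 (7.70 TPM in pup 1, 14.5 in pup 2) and Atf3 (5.61 and 9.56) against Fos (19.3 and 15.6), and the lists left out the differing genes Try4 (log2 ratio -1.07), Gm5771 (-1.23), Clca1, Nr4a2 (5.48 and 12.1) and Ier5l (1.53 and 3.78). These 3 explanations stay open, as do liver (0.80) and milk (0.67), which lay between the bounds. The milk value depends on the added 1 TPM as well: without it Wap, the middle member, was 2.00-fold higher in pup 2. That just reaches the bound of 1 for, so the verdict on milk turns on this choice.

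The adipose median (-0.14) met the bound against but rested on Fabp4 and Cidea, too few to decide. Adipose RNA in either stomach is argued against by Adipoq, Plin1, Lep and Ucp1, abundant in fat cells, which together had 3 counts in pup 1 and 5 in pup 2. Pups of different sex are argued against by Xist, whose log2 ratio was -0.0204; the Y-linked genes were at or under the floor in both pups, so the fold set for them could not be computed.

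Cdk5rap1 was higher in pup 2 in 7 of 7 annotated transcripts. Of reads shared with an overlapping or neighbouring gene, the overlapping part is argued against, since no annotated gene overlaps it and 0 overlapping genes rose. The bound written covered overlapping genes alone, so the neighbouring part stays open. Whether 1 transcript that starts inside the gene carried the rise cannot be told apart. Farthest inside, the retained intron transcript Cdk5rap1-207 starts 18666 bases downstream of the longest one and had 0.12 TPM in pup 1 and 3.91 in pup 2. Cdk5rap1-201 starts only 291 bases downstream, but outside the 49-base first exon of the longest transcript. It carried 55.2% of the rise, but the other transcripts together were 6.70 times higher as well, more than the bound for this explanation allowed. Only the longest transcript, Cdk5rap1-203, starts in that exon, at 0 TPM in pup 1 and 0.46 in pup 2. It carried 2.72% of the rise, under the share that the bound against needed. At so low a level that bound could hardly be met, so missing it decides nothing. A window of 500 bases from the first start, the rule run first, held 64.9%. A hypothesis is that the retrotransposon this gene is known to hold, whose methylation varies between genetically identical mice, may set the difference. Its methylation in both pups would decide, and was not analysed here.

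The levels of replication-dependent histone mRNA, which lacks a poly(A) tail, bear on how the cDNA was primed, since a kit for poly(A) priming is among the linked manuals. Summed histone TPM was 5.93 times that of the cell cycle genes in pup 1 and 5.12 times in pup 2. Both met the bound set against cDNA primed on poly(A) tails, a ratio of at least 3 in both pups. This rested on 1 gene, a limit noticed after the result: without Hist1h2ap the ratios were 2.31 and 2.18, between the bounds of 0.5 and 3. By these bounds the ratios without Hist1h2ap decide nothing. The levels of Rn7s1 (13335 TPM), Rn7sk (315) and Rpph1 (121) show that some RNA without a poly(A) tail was read. The medians of the histone list and of the short noncoding RNA list were only 2.44 and 6.59 TPM. A few members of a class seen do not exclude a lower yield of it, so how the cDNA was primed stays open.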
